A study of Mus musculus with 2 samples.

How the data were processed

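The series holds 2 single-cell RNA-seq libraries of microglia, the resident macrophages of the brain, from mice given cuprizone for 4 weeks. Cuprizone is a copper chelator that kills oligodendrocytes and strips myelin from the corpus callosum, the large white matter tract that joins the hemispheres. 1 library was made from the medial and 1 from the lateral corpus callosum, so the design holds 1 comparison, medial against lateral, with 1 library per region. Per the labels, the mice were of the C57Bl6 strain with the genotype CX3CR1; which allele they carried, how many mice gave each library and which gate was used in the sort are not given in the sources used here. Per the labels' protocols, tissue was dissociated with GentleMACS and cells were sorted by flow cytometry and loaded uncultured on a 10x Chromium controller for 3' libraries. Per the labels, sequencing was done on a NextSeq 500 with transcript reads of 57 bp for both samples.

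The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, for 27998 genes and 737280 barcodes in each library, so barcodes without a cell are included. Per the submitters' processing notes, Cell Ranger 2.0.1, STAR and mm10 were used; the gene annotation version is not given in the sources used here. The 56 gene symbols carried by more than 1 gene ID were summed by symbol, a choice made after the data were seen. No normalisation had been applied to the deposited counts.

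Cells were called here. A barcode was kept when its UMI total was at least 0.1 of the 99th percentile of the top 3000 barcodes of its library, the Cell Ranger 2 rule, which came to 2384 UMIs in the medial and 2379 in the lateral library, with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. The mitochondrial limit removed 3 barcodes in each library. Scrublet, as called from scanpy 1.11.5 with an expected doublet rate of 0.05, marked 7 medial and 0 lateral barcodes, which were left out; a doublet of a pair of microglia can escape it. Kept cells of both libraries were clustered together in scanpy. Settings were counts per 10000, log1p, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.3, run through igraph. Clusters were named from marker lists of 16 cell classes fixed beforehand.

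UMIs were summed over the microglia-like cells of each library and given as counts scaled to a fixed library total (CPM). A ratio is medial over lateral, with an exact conditional binomial 95% interval; CPM values have exact Poisson intervals and shares of cells exact Clopper-Pearson ones. These intervals cover counting error only. With 1 library per region no test between regions was possible, and no p-value, standard error or count of changed genes is given; cells are not replicates. The design, the gene lists and the rule for named genes were fixed before the data were examined.

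The 21 gene lists were homeostatic microglia, disease-associated microglia, interferon response, MHC class I, MHC class II, cholesterol synthesis, lipid handling and LXR targets, lysosome, phagocytic and complement receptors, complement components, cytokines and NF-kB, growth and repair factors, CSF1R and microglial transcription factors, proliferation, dissociation and immediate early genes, glycolysis and hypoxia, oxidative phosphorylation, antioxidant with iron and metal genes, unfolded protein and integrated stress, mitochondrially encoded, and sex-linked. A list's value is the median log2 ratio of its members with at least 30 UMIs over both libraries, with a 95% interval from 2000 Poisson resamplings of the UMIs. Its percentile is taken among 10000 random lists of the same size matched on mean expression in 20 bins, and describes these 2 libraries. For each list it is also counted how many members had a whole interval above or below a ratio of 1; this count of members is a description, not a test.

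Genes were named by size. Among genes with at least 100 UMIs, without mitochondrially encoded, ribosomal protein and sex-linked genes and unnamed gene models, the 15 higher and the 15 lower in the medial library were taken, ranked by the interval bound nearest a ratio of 1. From each list came the 2 measured members with the bound farthest from 1 in each direction and the 1 with most UMIs. Cx3cr1, P2ry12, Tmem119, Csf1r, Trem2, Apoe, Axl, Itgax, Lgals3, Spp1, Lpl, Cst7, Igf1, Mki67, Mbp, Xist and Ddx3y were among those to be given always. Some genes that the rule takes are not reported here. Clec7a, also in that rule, was not analysed here, nor were Trbc2, Trac, Ighm, Ighd, Igkc and Iglc2 of the marker lists.

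For per-cell values each cell was thinned to 3864 UMIs, the 10th percentile of the shallower library, which left out 132 medial and 231 lateral cells. A cell counted as one with proliferation transcripts when it held at least 3 UMIs from at least 2 of the named cycling genes. Microglia-like cells were re-clustered at resolution 0.6 without the 6510 detected genes whose ratio exceeded 1.2 either way or that had UMIs in 1 library only, and without sex-linked, mitochondrial and ribosomal protein genes, so that genes with such ratios did not set the sizes of sub-clusters; 1797 genes with smaller ratios whose interval excluded 1 were kept. Free RNA, released from broken cells, was read from barcodes with at most 50 UMIs. To find genes that share sequence, the last 500 nt of the transcripts of 9842 genes were searched in the GENCODE vM21 transcripts. A shared window was one of 57 nt also found in another gene, on either strand. The search does not tell near-identical copies from other genes that share sequence, such as overlapping ones. Gene positions are those of GRCm38 in the same annotation, matched by gene ID and counted from 1.

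The ratio and list calculations were tested on simulated data made from the 9842 genes with at least 100 UMIs. Intervals covered the true ratio for 98% of 200 changed genes and for 95.2% of the unchanged ones, and the median log2 ratios of genes made 1.5 times higher and lower were 0.58 and -0.59. The simulated counts were Poisson draws per gene and library, the model the intervals assume, without variation between cells. Coverage near 95% was therefore built in and does not show that the intervals hold for counts that vary between cells. Unchanged random lists should average a percentile of 50. A first run with 40 such lists averaged 40.4; the number was then raised to 200, the first 40 included, and the mean was 47.3 with a standard error of 2.11. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for its TMM scaling alone.

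Alternatives covered cell calling (at least 1000 or 2000 UMIs, at most 5% mitochondrial UMIs, doublets kept), clustering resolution (0.15 and 0.8, and 0.4 for sub-clusters), scaling (TMM, without mitochondrial and ribosomal protein genes, centred on the median gene), equal weight per cell, thinning, subtraction of free RNA, another UMI minimum for list members (300 or none), summed UMIs of a list in place of its median, and sub-clusters made with no gene left out on its ratio. Alternatives chosen after the data were seen are named with their results.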

Results

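Microglia sorted from the medial and from the lateral corpus callosum of mice after 4 weeks of cuprizone were profiled in 1 single-cell library per region. The medial library held 28660496 UMIs and the lateral 27955414, of which 81.8% and 82.5% lay in called barcodes. After filtering, 2125 medial and 2310 lateral cells remained, with medians of 10720 and 9692 UMIs and 2787 and 2642.5 genes per cell. Mitochondrial transcripts made up a median of 2.23% of UMIs per medial cell and 2.48% per lateral cell. There were no replicates, so every difference below compares 2 libraries, and each interval in parentheses is a 95% interval for counting error alone.

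The cells, which had been sorted, clustered as microglia in both libraries. All 5 clusters were microglia-like, so that the share was 100% in each library, with lower bounds of 99.8% for both. Those bounds count cells, while the class was given per cluster, so they leave out the uncertainty of the cluster names. With cells called at a minimum of 1000 UMIs the shares were 55.03% and 56.1%, because the largest cluster then held the border macrophage marker Ms4a7 among its leading genes and stayed unnamed. A set of at least 3 monocyte markers over 0.3% of UMIs was found in 1 medial cell, and such a set of neuron markers in 1 lateral cell, by limits chosen after the data were seen. Microglial markers made up 424 of 10000 UMIs in medial cells and 434 in lateral cells. The other 15 marker lists were low in cells of both libraries. Endothelial markers came to 1.82 medial and 1.65 lateral per 10000 UMIs, border macrophage markers to 1.64 and 1.54, neutrophil markers to 1.14 and 1.18, and monocyte markers to 1.10 and 1.13. Oligodendrocyte markers stood at 0.781 and 0.768 per 10000, astrocyte markers at 0.633 and 0.677, B cell markers at 0.242 and 0.168, mural cell markers at 0.142 and 0.140, and oligodendrocyte precursor markers at 0.139 and 0.131. Erythroid markers were at 0.0840 and 0.0937, dendritic cell markers at 0.0610 and 0.0468, and neuron markers at 0.0524 and 0.0668. T or NK cell markers were at 0.0264 and 0.0173, ependymal markers at 0.0179 and 0.0173, and fibroblast markers at 0.00128 and 0.00347. Mbp, a myelin transcript, was at 11.6 CPM in medial (10.3 to 13.1) and 12.5 CPM in lateral cells (11.1 to 14.0). Its level in free RNA was 12.8 and 10.5 CPM. The Y-linked Ddx3y was at 63.2 CPM in the medial and 61.0 in the lateral library, log2 ratio 0.05 (-0.06 to 0.16), whereas Xist, transcribed from the inactive X chromosome, reached 0.0856 and 0.564 CPM. The measured sex-linked genes had a median log2 ratio of -0.06, and for 4 of 4, Eif2s3y and Uty among them (43.6 and 10.9 CPM medial, 45.6 and 12.1 CPM lateral), the interval held a ratio of 1.

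The comparison asks how microglia of the medial and lateral corpus callosum differ during demyelination. The 2 libraries were close to each other across most genes and differed in a few programmes. Most immediate early genes were higher in the medial library, with the whole interval above a ratio of 1 for 26 of 29. So were most genes of the cytokine and NF-kB list, with 26 of 33 by the same measure. It also held for 14 of 28 interferon-response genes, 4 of 8 MHC class II genes, Apoe and Apoc1. Most cell cycle genes were higher in the lateral library, with the whole interval below a ratio of 1 for 25 of 32. So were 13 of 21 glycolysis and hypoxia genes by that measure, and several disease-associated genes, among them Spp1, Igf1, Lpl and Cst7. Of 9842 genes with at least 100 UMIs, 85.1% lay within a ratio of 1.2 and 97.8% within 1.5. The central 95% of log2 ratios ran from -0.40 to 0.47 around a median of -0.04. The log10 of summed UMIs plus 1 correlated at r = 0.994 across genes, which are not independent replicates.

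Most genes of the immediate early response, which tissue dissociation is known to induce, were higher in the medial library. Of 29 measured members of that list, 26 had an interval above a ratio of 1, 1 below it and 2 including it, and the median log2 ratio was 0.38 (0.37 to 0.42), at percentile 100 of the random lists. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, GRCm38), an immediate early zinc finger factor, was at 175 CPM medial and 108 CPM lateral, log2 ratio 0.69 (0.62 to 0.76). Jun, an AP-1 subunit, was at 488 and 331 CPM, log2 ratio 0.56 (0.52 to 0.60). The most abundant member, the chaperone Hspa8, was at 2002 and 1834 CPM, with 60.2% of its 57-nt windows shared with other genes. Klf2, a Krüppel-like factor, was lower in the medial library, at 114 against 143 CPM, log2 ratio -0.33 (-0.40 to -0.25), and Hsp90aa1 was at 190 and 196 CPM (39.3% of windows shared). Per cell at 3864 UMIs, the list took a median of 1.22% of UMIs in medial and 0.983% in lateral cells.

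Most cytokine and NF-kB genes were also higher in the medial library. Of 33 members, 26 had an interval above a ratio of 1 and 3 below it, and the median log2 ratio was 0.19 (0.16 to 0.27), at percentile 100. Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), a neutrophil-attracting chemokine, was at 795 CPM medial and 482 CPM lateral, log2 ratio 0.72 (0.69 to 0.76). The chemokine Ccl3, which the immediate early list also holds, was at 1105 and 767 CPM, log2 ratio 0.53 (0.50 to 0.55). Cd83, an activation marker and the most abundant member, was nearer equal, at 2225 and 2129 CPM. The interferon-gamma-induced chemokine Cxcl9 went the other way, at 5.05 and 8.24 CPM, log2 ratio -0.71 (-1.05 to -0.37), as did Cxcl14 at 110 and 124 CPM. Without the 4 members shared with the immediate early list, a choice made after the data were seen, the median was 0.18, and 22 of 29 members had an interval above a ratio of 1. The immediate early list was higher in the same library by 0.38, as given above.

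The medians of interferon-response genes and MHC class II genes lay on the medial side, while the median of MHC class I genes was near 0. Of 28 interferon-response genes, 14 had an interval above a ratio of 1, 0 below it and 14 including it, with a median log2 ratio of 0.18 (0.12 to 0.23) at percentile 100. Slfn2 (ENSMUSG00000072620, chromosome 11, 83065112 to 83070678), a Schlafen family gene, was at 296 CPM medial and 199 CPM lateral, log2 ratio 0.57 (0.52 to 0.63), and Slfn5 was at 9.55 and 5.60 CPM, log2 ratio 0.77 (0.45 to 1.09). Ifi27l2a, the most abundant member, was at 846 and 819 CPM, Bst2 at 418 and 413 CPM, and Ifit1 at 8.99 and 10.6 CPM. With cells called at a minimum of 1000 UMIs the interferon median was 0.021, since a cluster led by Ifit3 and Spp1 then stayed unnamed and 55.03% of medial and 56.1% of lateral cells remained in the sums. With that cluster kept, a choice made after the data were seen, it was 0.18. Of 8 measured MHC class II genes, which present antigen to CD4 T cells, 4 had an interval above a ratio of 1, 1 below it and 3 including it, with a median of 0.23 (0.13 to 0.28) at percentile 99.98. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the invariant chain of class II molecules, was at 687 and 515 CPM, log2 ratio 0.42 (0.38 to 0.45), and H2-Eb1 at 79.1 and 64.5 CPM, log2 ratio 0.29 (0.19 to 0.39). H2-DMa, which helps load peptides, was at 223 and 243 CPM, log2 ratio -0.13 (-0.18 to -0.07), and H2-DMb1 at 131 and 132 CPM (25.1% of windows shared). When each cell counted alike the class II median was 0.43. The per-cell median share of class II UMIs was 0.0518% in both libraries, about the level of 2 UMIs, and the 95th percentile was 0.606% medial and 0.362% lateral. Interferon-response genes took a median of 0.207% in both. MHC class I genes had a median log2 ratio of -0.02 (-0.06 to 0.02), at percentile 64.6. Of 14, 1 had an interval above a ratio of 1 and 4 below it. The median was 0.066 when each cell counted alike and -0.12 for summed UMIs. B2m, the shared light chain, was at 5786 and 6443 CPM, log2 ratio -0.16. H2-D1 was at 1849 and 1954 CPM, with its direction turned when each cell counted alike (0.013). H2-Q4 was at 31.7 and 28.2 CPM (21.96% of windows shared) and H2-Q7 at 49.7 and 46.8 CPM. The per-cell median of class I genes was 0.854% in medial and 0.906% in lateral cells.

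**Figure D1:**
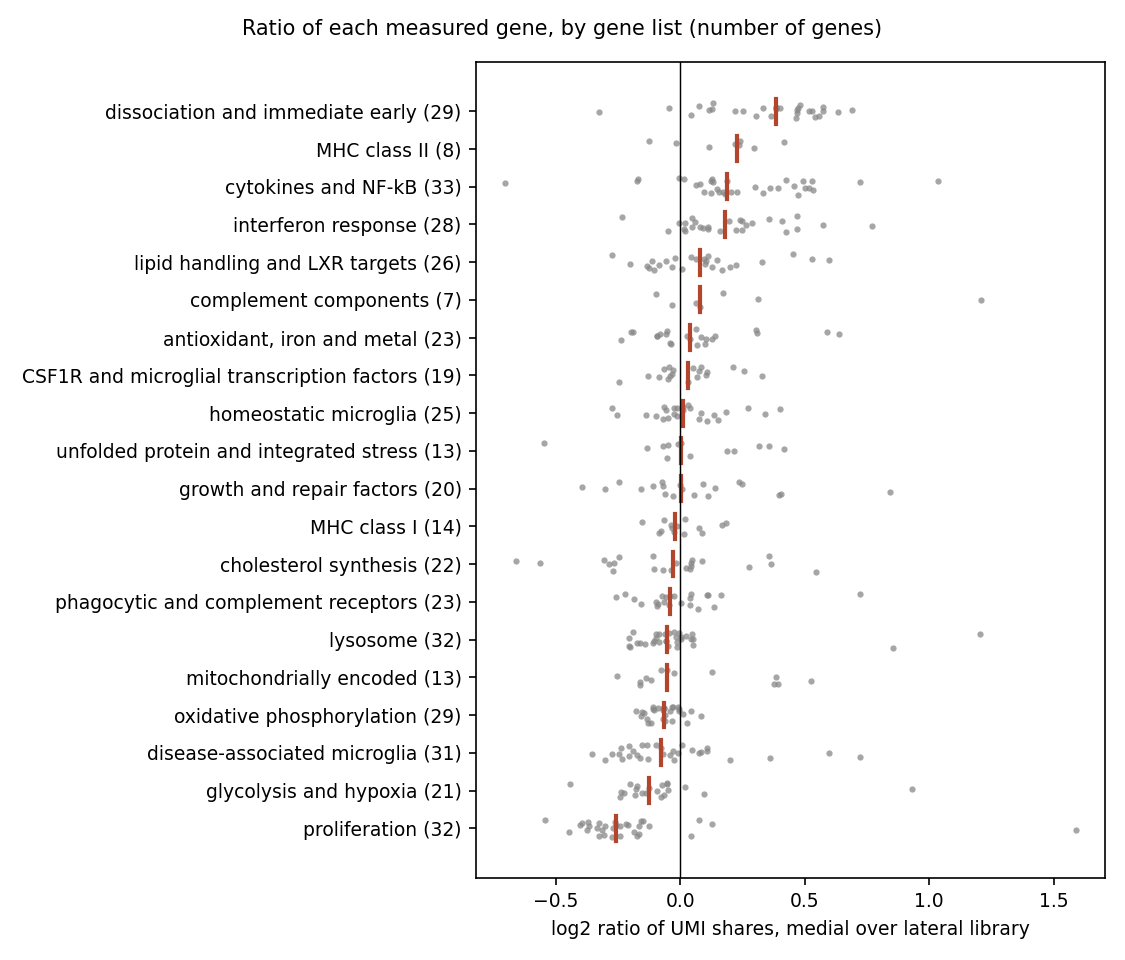
Each point is the log2 ratio (medial over lateral CPM, x axis) of 1 measured gene, grouped by gene list (y axis, number of measured genes in parentheses), and the bar marks the list median, for the 20 lists other than the sex-linked one. Medians run from -0.26 for proliferation to 0.38 for immediate early genes.

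Disease-associated microglial genes, the set that microglia switch on around damaged tissue, were split between the libraries. Of 31 measured members, 9 had an interval above a ratio of 1, 18 below it and 4 including it, with a median log2 ratio of -0.08 (-0.11 to -0.05) at percentile 4.14. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, was at 4547 CPM medial and 5395 CPM lateral, log2 ratio -0.25 (-0.26 to -0.24). Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042), a growth factor for oligodendrocyte lineage cells, was at 435 and 536 CPM, log2 ratio -0.30 (-0.34 to -0.26). Lipoprotein lipase, Lpl, was at 716 and 865 CPM, log2 ratio -0.27, and the cystatin Cst7 at 1099 and 1296 CPM, log2 ratio -0.24. The chemokine Ccl6 was at 601 and 770 CPM, log2 ratio -0.36 (-0.39 to -0.32). Itgax (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657), an integrin alpha chain, was higher in the medial library, at 35.0 and 21.2 CPM, log2 ratio 0.72 (0.56 to 0.89). So was Ch25h, an oxysterol-forming hydroxylase, at 75.9 and 50.1 CPM, log2 ratio 0.60 (0.49 to 0.71). Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the main lipid carrier of the brain, was the most abundant member, at 47285 and 41171 CPM, log2 ratio 0.20 (0.20 to 0.20). The summed UMIs of the list, Apoe included, had a log2 ratio of 0.021, opposite in sign to the median, and the per-cell median share was 13.2% in medial and 12.8% in lateral cells. The lipid and damage receptor Trem2 was at 2655 and 2730 CPM, log2 ratio -0.04 (-0.06 to -0.02), and the receptor kinase Axl at 288 and 293 CPM, log2 ratio -0.03 (-0.07 to 0.02). Lgals3, a galectin, was at 314 and 330 CPM, log2 ratio -0.07, which was 0.017 with cells thinned to 1 depth.

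Lipid handling, lysosomal, phagocytic and complement genes each went both ways. Of 26 lipid handling genes and LXR targets, 9 had an interval above a ratio of 1 and 7 below it, with a median log2 ratio of 0.08 (-0.00 to 0.10) at percentile 99.96. The list took 5.26% of medial and 4.66% of lateral UMIs, most of it Apoe. Apoc1 (ENSMUSG00000040564, chromosome 7, 19689481 to 19692660), a neighbour of Apoe on the same strand, was at 347 and 241 CPM, log2 ratio 0.53 (0.48 to 0.58), whereas Fabp5, a fatty acid binding protein, was at 489 and 537 CPM. Of 32 lysosomal genes, 5 had an interval above a ratio of 1 and 19 below it, with a median of -0.06 (-0.07 to -0.04) at percentile 20.7, near the median of -0.04 over all genes. The cathepsin Ctsb was at 9373 and 10816 CPM (33.3% of windows shared) and Cd68 at 1218 and 1407 CPM, both with a log2 ratio of -0.21, while Ctsd was at 29059.9 and 28169.9 CPM, log2 ratio 0.04. The proton pump subunits Atp6v0c, at 2.70 and 1.17 CPM, and Atp6v0d2, at 6.04 and 3.34 CPM, were higher in the medial library. Of 23 phagocytic and complement receptors, 4 had an interval above a ratio of 1 and 10 below it, with a median of -0.04 (-0.05 to -0.00) at percentile 47.6. The scavenger receptor Scarb1 was at 75.2 and 90.1 CPM, the Fc receptor Fcgr3 at 1048 and 1191 CPM, and the anaphylatoxin receptor C3ar1 at 214 and 191 CPM. Of 7 complement components, 2 had an interval above a ratio of 1 and 2 below it, with a median of 0.08 (0.02 to 0.14) at percentile 93.04, which turned to -0.020 for summed UMIs. C3, the central complement component, was at 5.01 and 2.17 CPM, log2 ratio 1.21 (0.72 to 1.72). The C1q chains were close to equal: C1qa was at 8773 and 8394 CPM, C1qc at 7894 and 8447 CPM, and C1qb at 8182 and 8368 CPM, log2 ratio -0.03. That direction turned when each cell counted alike (0.000245) and at a minimum of 1000 UMIs (0.022), and under centring, which shifts all ratios alike by 0.04.

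Homeostatic microglial genes, which mark microglia of undamaged brain, went both ways around a median near 0. Of 25, 10 had an interval above a ratio of 1, 6 below it and 9 including it, with a median log2 ratio of 0.01 (-0.02 to 0.03) at percentile 91.7, which was 0.046 when ratios were centred on the median gene, and the per-cell median share was 2.1998% in medial and 2.17% in lateral cells. Tmem119 was at 523 and 512 CPM, log2 ratio 0.03 (-0.01 to 0.07), and the fractalkine receptor Cx3cr1 at 362 and 365 CPM, log2 ratio -0.01 (-0.06 to 0.03). The ADP receptor P2ry12 was slightly lower in the medial library, at 412 and 454 CPM, log2 ratio -0.14 (-0.18 to -0.10). Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), an Fc receptor-like gene, was at 1608 and 1944 CPM, log2 ratio -0.27 (-0.29 to -0.25), and the fructose transporter Slc2a5 at 34.8 and 41.5 CPM, log2 ratio -0.26. On the medial side were Rhob, at 328 and 248 CPM, log2 ratio 0.40, which the immediate early list also holds, and the crystallin Crybb1, at 75.9 and 60.04 CPM, log2 ratio 0.34. Cst3, cystatin C, was the most abundant member, at 9223 and 8974 CPM, log2 ratio 0.04. Of 19 genes of the CSF1R and transcription factor list, 8 had an interval above a ratio of 1 and 4 below it, with a median of 0.03 (-0.03 to 0.07) at percentile 96.1. Csf1r, the receptor that microglia depend on, was at 1028 and 971 CPM, Cebpa at 124 and 104 CPM, Runx1 at 91.4 and 79.0 CPM, the adaptor Tyrobp at 6407 and 7017 CPM, and Bhlhe41 at 165 and 195 CPM (60.7% of windows shared). Of 20 growth and repair factors, 5 had an interval above a ratio of 1 and 6 below it. Their median was 0.0031 (-0.04 to 0.05) at percentile 82.1. The EGF family member Hbegf, at 7.24 and 4.03 CPM, and the interleukin-1 antagonist Il1rn, at 64.1 and 48.5 CPM, were higher in the medial library. The summed UMIs of this list, most of them from Spp1, had a log2 ratio of -0.16.

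Most cell cycle genes and glycolytic enzymes were lower in the medial library. Of 32 proliferation genes, 25 had an interval below a ratio of 1, 2 above it and 5 including it, with a median log2 ratio of -0.26 (-0.29 to -0.21), at percentile 0 of the random lists. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of cycling cells, was at 29.1 CPM medial and 35.9 CPM lateral, log2 ratio -0.31 (-0.45 to -0.16), and at 23.1 and 20.2 CPM in free RNA. The kinetochore gene Cenpf was at 18.7 and 25.5 CPM, log2 ratio -0.45 (-0.63 to -0.27), Cks1b at 55.1 and 71.5 CPM, log2 ratio -0.38, and the abundant histone variant H2afz at 896 and 1006 CPM (49.5% of windows shared). Pcna, a replication clamp, was at 70.0 and 64.1 CPM, and Hist1h2ap, which shares 92.96% of its 57-nt windows with other genes, was at 10.1 and 3.34 CPM. Cells with proliferation transcripts made up 10.5% of medial cells (9.18 to 11.9, 209 cells) and 13.3% of lateral cells (11.9 to 14.9, 277 cells) at 3864 UMIs per cell; unthinned shares were 17.7% and 18.8%. Proliferation genes took a median of 0.207% of UMIs per medial and 0.233% per lateral cell. Of 21 glycolysis and hypoxia genes, 13 had an interval below a ratio of 1 and 1 above it, with a median of -0.13 (-0.18 to -0.10) at percentile 0.330; without members that share over 20% of their windows, a choice made after the data were seen, it was -0.076. Gapdh was at 1346 and 1577 CPM, log2 ratio -0.23 (-0.25 to -0.21), with 42.4% of its windows shared with another gene. The prolyl hydroxylase Egln3 was at 24.8 and 33.7 CPM, log2 ratio -0.45 (-0.60 to -0.29), and hexokinase Hk2 at 78.6 and 73.6 CPM. The gene with its whole interval above a ratio of 1 was Pgk1, at 36.3 and 19.0 CPM, with 39.1% shared. Of 29 nuclear oxidative phosphorylation genes, 18 had an interval below a ratio of 1 and 1 above it, with a median of -0.07 (-0.09 to -0.05) at percentile 9.96. Cytochrome c, Cycs, was at 143 and 162 CPM (30.5% of windows shared), Ndufa1 at 348 and 388 CPM, Atp5b at 438 and 413 CPM, Atp5d at 299 and 293 CPM and Cox4i1 at 1353 and 1357 CPM. Of 13 mitochondrially encoded genes, 5 had an interval above a ratio of 1 and 7 below it. Their median was -0.06 (-0.07 to -0.04) at percentile 31.3. mt-Atp6, with 99.3% of its windows shared, was at 5951 and 7094 CPM and mt-Nd1 at 2479 and 2778 CPM. mt-Nd4l, with 98.8% shared, was at 201 and 153 CPM. mt-Atp8 was at 31.8 and 22.1 CPM.

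Among single genes named by the size of their ratio, Vcam1, Mbd2, Bcl2a1c and C3 stood on the medial side and Cd5l, Slpi and Igfbp5 on the lateral side. Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), a leukocyte adhesion molecule, was at 23.8 CPM medial and 12.1 CPM lateral, log2 ratio 0.97 (0.76 to 1.19), and at 32.1 and 18.3 CPM in free RNA. The methyl-CpG binding gene Mbd2 was at 34.6 and 17.1 CPM, log2 ratio 1.01 (0.84 to 1.19), and Hnrnpa0 at 75.1 and 42.6 CPM, log2 ratio 0.82 (0.70 to 0.93). The transcription factor Ebf1 was at 10.1 and 4.86 CPM, log2 ratio 1.06 (0.73 to 1.40). The low-level Timm8a1 and Glra1 were at 4.07 and 4.24 CPM medial against 1.39 and 1.74 CPM lateral. Bcl2a1c, a survival gene of a family of close copies, was at 40.1 and 14.9 CPM, log2 ratio 1.43 (1.25 to 1.61), with 8.25% of its windows shared. Of the 15 highest, 6 genes share over 20% of their windows with another gene, against 11.5% of all genes searched. Among those 6 were AY036118 at 32.7 and 10.2 CPM (100% shared), Hist1h2ap, Nme2 at 24.1 and 10.5 CPM (98.9%), Gng10 at 25.3 and 11.1 CPM (96.6%) and Pgk1. CAAA01147332.1, at 3.81 and 1.30 CPM, had no transcript in the annotation searched. On the lateral side, Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), a secreted macrophage scavenger protein, was at 11.99 and 23.3 CPM, log2 ratio -0.96 (-1.17 to -0.75). The protease inhibitor Slpi was at 9.16 and 17.4 CPM, log2 ratio -0.92 (-1.17 to -0.68), and Igfbp5, an insulin-like growth factor binding protein, was at 2.10 and 5.03 CPM, log2 ratio -1.26 (-1.77 to -0.77). Fabp7 (ENSMUSG00000019874, chromosome 10, 57784881 to 57788450), a radial glia and astrocyte gene, was at 1.24 and 3.64 CPM in cells, but at 48.4 and 118 CPM in free RNA, so its level in cells lies below that of the free RNA around them. Hjurp, Cep55, Ndc80 and Dtl, which act in cell division or DNA replication, and the histone Hist1h1e (99.1% of windows shared) had log2 ratios from -0.80 to -0.68. The other lateral genes were Cxcl9, given above, Perp at -0.68, Plp2 at -0.76 (65.9% shared), Sfxn5 at -0.92, Rbks at -0.73 and the interferon-induced GTPase Iigp1 at -0.77.

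**Figure D2:**
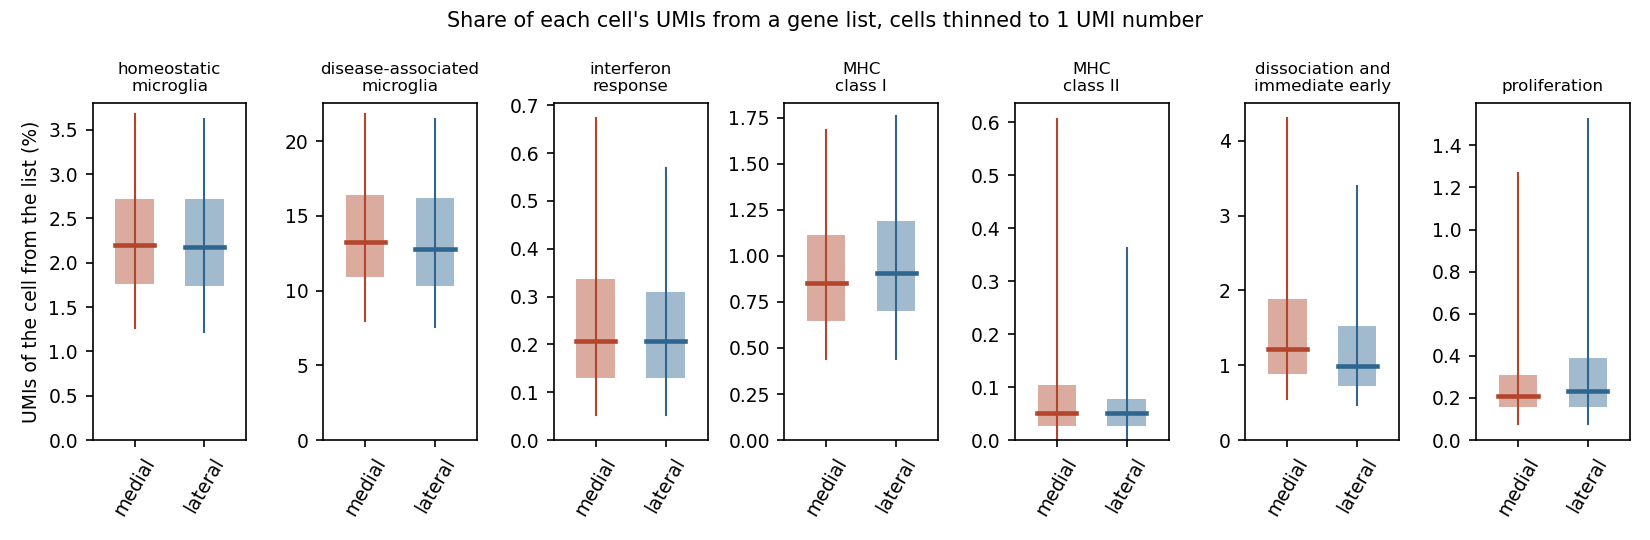
Share of UMIs per cell (percent, y axis) for 7 gene lists in medial and lateral cells, each thinned to 3864 UMIs (1993 medial and 2079 lateral cells). Boxes give the quartiles, thick lines the median and thin lines the 5th to 95th percentile over cells; the immediate early median is 1.22% in medial and 0.983% in lateral cells.

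Re-clustering without the genes whose ratio exceeded 1.2 either way gave 7 sub-clusters, all with microglial markers and present in both libraries. Sub-cluster 4, led by the class II genes Cd74, H2-Aa and H2-Eb1 with Itgax and Ifit3, held 19.8% of medial cells (18.1 to 21.5) and 11.2% of lateral cells (9.95 to 12.6), a difference of 8.55 percentage points (6.43 to 10.7). With no gene left out on its ratio its counterpart was smaller, at 7.76% and 4.42%, a difference of 3.35 points (overlap 0.329). H2-Aa and H2-Ab1, both higher in the medial library by a ratio under 1.2, had not been left out of the main run. With genes whose interval excluded a ratio of 1 left out too, a choice made after the data were seen, its counterpart held 20.7% and 15.2%, a difference of 5.51 points. Sub-cluster 3, led by Actb and Slc39a1, held 19.7% of medial and 27.7% of lateral cells, a difference of -8.04 points (-10.5 to -5.54). Its lateral cells were the shallower ones, with medians of 8382 medial and 5884.5 lateral UMIs, and with no gene left out the difference was -4.32. Sub-cluster 5, led by Fos, Jun and Egr1, held 11.1% and 8.31% of cells. Sub-cluster 2, led by Lgals1, Gpnmb and Spp1, held 20.4% and 23.3%. Under that stricter choice its cells were spread, with a best overlap (Jaccard index) of 0.267 with a group led by Il12b, while a group led by Cd5l, Actb and Gpnmb held 25.3% and 31.7%. Sub-cluster 6, led by Top2a, which had not been left out on its ratio either, and other cycling genes, held 7.62% and 9.18%. Sub-cluster 1, led by Crybb1, Siglech and P2ry12, held 20.5% and 19.9%, a difference of 0.557 points. With no gene left out on its ratio its best overlap was 0.266, with a group of 7.95% and 14.1% led by Sox11 and Crybb1. Sox11 had UMIs in only 6 medial and 12 lateral cells of the whole libraries, so it does not describe most cells of that group. Sub-cluster 7, led by Ccl5 and Apoc1, held 21 medial and 9 lateral cells and had no counterpart under the alternatives. Within sub-clusters, the cytokine list had a median log2 ratio above 0 in 7 of 7, from 0.09 to 0.25, with an interval that held 0 in 2 of them, sub-clusters 4 and 7. The immediate early list had its whole interval above 0 in 6 of 7, with the exception in sub-cluster 7. The class II list had its whole interval below 0 in 5 of 7, at -0.25 in sub-cluster 1, -0.41 in 2, -0.20 in 3, -0.45 in 6 and -2.83 in the 30 cells of 7. It held 0 in sub-cluster 4, at -0.04 (-0.07 to 0.07), and in sub-cluster 5, at 0.22 (-0.02 to 0.44). Members with a ratio under 1.2 stayed among the genes from which the 2000 variable genes for clustering were taken, and so could shape the sub-clusters. Examples are H2-Aa of class II, Ifit1 and Bst2 of the interferon, Spp1 and Cst7 of the disease-associated and B2m of the class I list. Others are Cd83 of the cytokine, Hspa8 of the immediate early and Top2a of the proliferation list. Which of them were among the 2000 is not reported here. Values within sub-clusters therefore cannot show whether levels of a list differ between like cells. The class I list had its whole interval below 0 in 3 of 7, at -0.09 in sub-cluster 1, -0.14 in 2 and -0.12 in 3, and held 0 in 4. The disease-associated list had its whole interval below 0 in 5 of 7 and the proliferation list in 3 of 7, with 2 and 4 holding 0. The interferon list was above 0 in 5 of 7 and below it in sub-clusters 4, at -0.11 (-0.21 to -0.04), and 7.

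**Figure D3:**
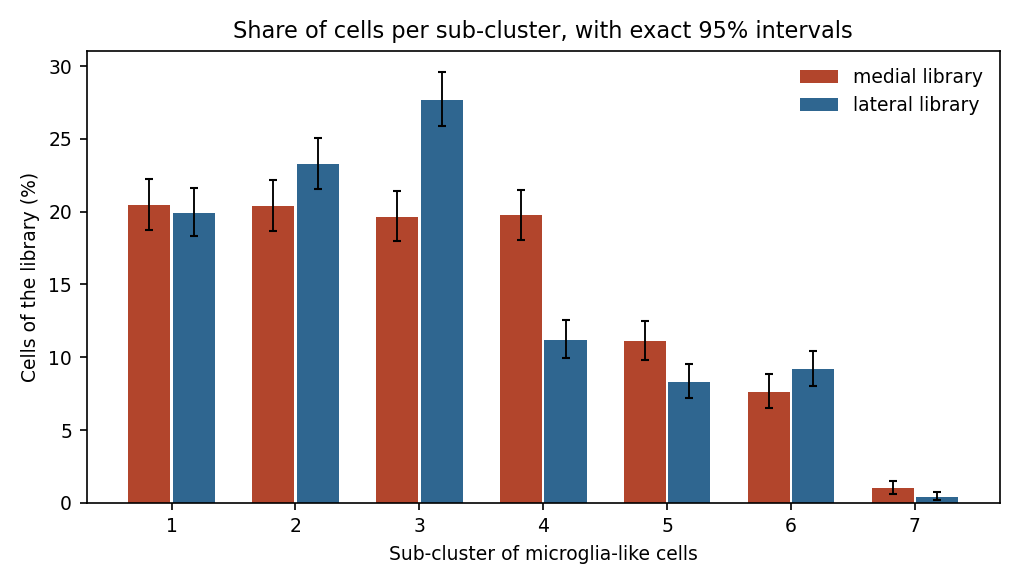
Percent of each library's cells (y axis) in 7 sub-clusters of microglia-like cells (x axis); bars are the medial and lateral library, and error bars are exact 95% binomial intervals for counting error. Sub-cluster 4 holds 19.8% of medial and 11.2% of lateral cells, and sub-cluster 3 holds 19.7% and 27.7%.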

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

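The 2 tests of explanations in this part were set before their results were seen; the value without Igfbpl1, the demand that the whole interval of the second test clear its bound, and the limits for cells with neuron markers were chosen after.

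Neuronal transcripts in the free RNA of the lateral library stood out in a library of sorted microglia, where 1 lateral and 0 medial cells carried at least 3 neuron markers over 0.3% of UMIs. The neuron list came to 0.841 per 10000 UMIs of lateral free RNA and 0.2996 of medial free RNA, with a limit from a count of 0 of 0.0117 in the lateral library, and most of it was Tubb3 (101 and 26 UMIs) and Stmn2 (79 and 27), 2 genes of neuronal processes; the lateral to medial ratio was 2.81 (2.13 to 3.73). RNA of subventricular zone neuroblasts, young neurons born along the ventricle wall beside the lateral corpus callosum, may have reached that suspension: 8 neuroblast genes together had a lateral to medial ratio of 2.15 (1.23 to 3.9002; 45 and 19 UMIs), but without Igfbpl1 the ratio was 1.44 (0.664 to 3.25), so the result of this list rests on that gene; Dcx of the list had 9 lateral and 2 medial UMIs in free RNA, a ratio of 4.09 (0.847 to 38.9) that holds 1, and 10 and 0 in cells, and Sox11, chosen after its values were seen, had 44 and 12 in free RNA and 90 and 7 in cells. Reads carried over from another library could not be ruled out: 6 of 216 neuron UMIs lay in barcodes with more than 1 of them, 8.62 times the share of a random spread, which is past the bound of 5 set beforehand, while the interval of 3.18 to 18.5 is not. That interval treats UMIs of the same barcode as independent, so it is too narrow. Such grouping also cannot tell carried-over reads from neuronal RNA that was held together in a droplet. With 1 library per region, a regional difference in the tissue, not tested here, stays open too.

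Hbb-bs, a beta globin transcript, had 585 UMIs and Hba-a1, an alpha globin transcript, had 258 UMIs among lateral barcodes under the cell threshold, each in 1 barcode, against 0 UMIs of either in such medial barcodes. Oligodendrocyte precursor markers came to 1.68 per 10000 UMIs in lateral barcodes under the threshold (1.24 to 2.23), above the limit of 0.105 that a count of 0 allows, and to 0.552 in the medial ones (0.315 to 0.896). Barcodes were counted for Olig1 alone of this list, whose 15 lateral UMIs lay in 5 of them. Other lists were also higher in the lateral barcodes under the threshold, such as neuron (1.47 lateral, 0.483 medial) and astrocyte markers (1.78 and 0.966). Mural (0.315 and 0.517), neutrophil (1.26 and 1.66) and microglial markers (548 and 621) were lower.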

How the results depend on the processing

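Alternatives were fixed before the data were examined, except that keeping unnamed clusters, leaving out cytokine members shared with the immediate early list, leaving out members with shared windows, subtracting free RNA at a limit set by Fabp7 and leaving genes with an interval off a ratio of 1 out of the sub-clustering were chosen after seeing the data. No paired analysis was possible because each region has 1 library and no test was run; for the same reason no replicate could be left out. The setting that used all retained cells moved nothing, since all cells were microglia-like. Of 1762 values of 126 single genes under alternatives, 1503 stayed within the counting interval, 252 moved outside it with the direction kept or not called, and 7 turned direction; of 449 values of lists, cells and sub-clusters the numbers were 379, 66 and 4. The medians of the MHC class II (0.14 to 0.43), cytokine (0.13 to 0.28), immediate early (0.31 to 0.42), interferon (0.02 to 0.21), lipid (0.04 to 0.17), proliferation (-0.33 to -0.20), glycolysis (-0.18 to -0.08), lysosome (-0.06 to -0.02), oxidative phosphorylation (-0.09 to -0.03) and mitochondrially encoded (-0.14 to -0.01) lists kept their sign under all alternatives run for each. Where no cause is given below, the cause was not tested. Depth limits the genes of a few CPM, and counting intervals leave out any difference between animals or preparations.

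At a limit of 5% mitochondrial UMIs the medians were 0.046 for homeostatic, -0.038 for lysosome, 0.13 for cytokine, -0.33 for proliferation, 0.35 for immediate early, -0.049 for unfolded protein and -0.083 for mitochondrially encoded genes, and microglia-like cells made up 87.3% of medial and 79.3% of lateral cells, because a cluster led by Gpnmb and Ms4a7 stayed unnamed. At a minimum of 1000 UMIs, 2228 medial cells were kept, and a cluster led by Ifit3, Spp1 and Ms4a7 stayed unnamed, which left 55.03% and 56.1% microglia-like; medians were 0.021 for interferon, -0.031 for lysosome, -0.31 for proliferation, -0.088 for oxidative phosphorylation and -0.073 for mitochondrially encoded genes, and C1qb turned to 0.022. With unnamed clusters kept, 126 of 126 single genes at 1000 UMIs and 123 of 126 at 5% stayed within the interval. At resolution 0.8 the microglia-like shares were 88.8% and 85.0%, again through an unnamed cluster.

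Scaling shifted all ratios alike, by 0.03 with TMM, 0.02 without mitochondrial and ribosomal protein genes and 0.04 with centring. TMM gave 0.042 for homeostatic, -0.045 for disease-associated, 0.11 for lipid, -0.023 for lysosome, -0.094 for glycolysis, -0.035 for oxidative phosphorylation and -0.024 for mitochondrially encoded genes. Centring gave 0.046, -0.042, 0.11, -0.019, -0.090, -0.032 and -0.020 for the same lists in that order, and turned C1qb to 0.0034. Without mitochondrial and ribosomal protein genes the lysosome and mitochondrially encoded medians were both -0.039.

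Ratios of summed UMIs, which follow a list's most abundant genes, were 0.021 for disease-associated (turned), -0.12 for MHC class I, 0.17 for lipid, -0.020 for complement (turned), 0.28 for cytokine, -0.16 for growth factor, -0.059 for CSF1R and transcription factor, -0.20 for proliferation, 0.31 for immediate early, -0.054 for antioxidant and -0.14 for mitochondrially encoded genes. With equal weight per cell the medians were 0.066 for MHC class I, 0.43 for MHC class II, -0.042 for lysosome and -0.18 for glycolysis, and C1qb (0.000245), H2-D1 (0.013) and Lgals3 (0.011) turned. With cells thinned to 1 depth they were 0.040 for MHC class I, 0.40 for MHC class II and -0.022 for lysosome, and Lgals3 turned to 0.017. With free RNA subtracted at shares of 25.1% medial and 14.2% lateral, set by the erythroid and neuron lists as planned, they were 0.032 for MHC class I, -0.040 for lysosome, 0.0085 for phagocytic receptors (turned), 0.16 for cytokine and -0.010 for mitochondrially encoded genes, and Cst3 turned to -0.0087. Those shares were too high, since Fabp7 limits them to 2.57% and 3.10% and Tubb3 to 5.002% and 4.19%, so these values are not a measure of the effect of free RNA. At the Fabp7 limits the phagocytic median was -0.038, Cst3 was at 0.043 and 125 of 125 single genes stayed within the interval. Without members with shared windows, glycolysis was at -0.076 and mitochondrially encoded genes at -0.028.

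Cells with proliferation transcripts were 13.04% medial and 16.3% lateral when thinned to the 25th percentile and 17.7% and 18.8% without thinning. With no gene left out of the clustering, the differences were -6.12 points for sub-cluster 1 (overlap 0.266), -4.32 for sub-cluster 3 (0.608) and 3.35 for sub-cluster 4 (0.329). With genes whose interval excluded 1 left out too the difference was 5.51 for sub-cluster 4, and 0.23 for the group nearest to sub-cluster 2, which with an overlap of 0.267 and other leading genes is not the same group of cells. At resolution 0.4 sub-cluster 1 joined a larger group, with -1.83. Sub-cluster 7 had no counterpart in any of these runs (best overlaps 0.0501, 0.0469 and 0.0168, under a minimum of 0.1 chosen after seeing the data) and so no value.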

Other observations

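The tests of explanations in this part were set before their results were seen; the genes counted in single lateral cells were chosen after their values were seen.

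Stress genes went both ways. Of 23 antioxidant, iron and metal genes, 8 had an interval above a ratio of 1 and 6 below it, with a median log2 ratio of 0.04 (-0.03 to 0.08) at percentile 98.02. The cystine transporter Slc7a11, at 68.7 CPM medial and 45.6 CPM lateral, log2 ratio 0.59 (0.48 to 0.70), and Srxn1, which repairs peroxiredoxins, at 14.0 and 8.98 CPM, log2 ratio 0.64 (0.38 to 0.89), were higher in the medial library, while the ferritin light chain Ftl1 was lower, at 10577 and 12133 CPM, log2 ratio -0.20 (70.6% of windows shared), and Gpx4 was at 629 and 666 CPM (55.8%). Of 13 unfolded protein and integrated stress genes, 4 had an interval above a ratio of 1 and 4 below it. Their median was 0.0032 (-0.02 to 0.07) at percentile 79.3. The stress transcription factor Atf4, at 150 and 117 CPM, and the chaperone partner Dnajb9, at 60.2 and 45.1 CPM, were higher in the medial library, Sdf2l1, at 606 and 665 CPM, was lower, Calr was at 764 and 793 CPM, and Hspa5 was at 1127 and 1124 CPM.

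Of 22 measured cholesterol synthesis genes, 2 had an interval above a ratio of 1, 5 below it and 15 including it, with a median of -0.03 (-0.16 to 0.04) at percentile 51.4. Insig1, which restrains sterol synthesis, was at 33.5 and 26.2 CPM and Cyp51 at 7.92 and 6.16 CPM, on the medial side, while Nsdhl, at 3.896 and 5.77 CPM, Dhcr7, at 11.6 and 14.2 CPM, and Ebp, at 65.1 and 70.1 CPM, were on the lateral side.

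Most immediate early and most cytokine genes were higher in the medial library. With cells thinned to 3864 UMIs the immediate early median was 0.40 (0.36 to 0.44), above the bound of 0.3 set beforehand. Thinning keeps each gene's expected share of a cell's UMIs, so this test could not decide whether depth caused the difference. It shows only that the difference was kept at equal depth with the shallowest cells left out. A response to dissociation may carry part of the cytokine difference: among 1689 cells per library matched on immediate early share, where the immediate early median was 0.06, the cytokine median was 0.098 as the median of 100 draws (counting interval of the first draw 0.055 to 0.20), which is 52.7% of its value over all cells and between the bounds set for and against that explanation. Over those draws the matched median ran from 0.031 to 0.15, past both bounds, so the test decides nothing. The matched cells were thinned to 3864 UMIs, while the value over all cells came from unthinned ones. Over all thinned cells the cytokine median was 0.20. The regions cannot be told apart from their preparation with 1 library each, so a regional difference in microglial activation, not tested here, stays open beside it.

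Genes that share windows with another gene were frequent among the highest medial to lateral ratios, but most were not shifted. The median log2 ratio was -0.02 over genes that share over 20% of their windows and -0.04 over genes with none shared. Among 1126 genes that share over 20% of their windows, 4.88% had a ratio over 1.5 either way, 2.67 times (2.02 to 3.45) the 1.83% of genes with none matched on UMIs, between the bounds set beforehand; 50 of those 55 were higher in the medial library, against 70 of 115 among genes with none shared. A different split of shared reads could produce more large ratios. Its test counted ratios either way, so it does not address why 50 of those 55 were higher in the medial library. A longer read in the medial library might also produce large ratios, as it would place more reads in 1 gene. The labels record 57 bp for both libraries, however. The 55 genes that lose over 20 points of shared windows at 98 nt had a median log2 ratio of 0.12 (0.08 to 0.17), between the bounds set for and against a longer read. Both explanations and a biological difference in these genes, not tested here, stay open.

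Of 6 neuroblast, neuron and radial glia genes looked at in lateral cells, some lay in few cells and others were spread. Sox11 had 90 UMIs in 12 cells, 47 of them in 1 cell, Igfbpl1 57 UMIs in 9 cells and Dcx 10 UMIs in 6 cells, against 7, 6 and 0 UMIs in medial cells. Tubb3 had 38 UMIs in 17 lateral cells, 20 of them in 1 cell, while Stmn2 had 48 UMIs in 43 cells and Fabp7 84 UMIs in 80 cells.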
